A study of Mus musculus with 4 samples.

How the data were processed

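The 4 libraries were made by translating ribosome affinity purification (TRAP) from the rostral pons of adult mice of the Cbln2-TRAP line NIDA172, which carries ribosomal protein L10a fused to EGFP. In TRAP, antibodies against EGFP pull down tagged ribosomes together with the RNA bound to them, which is meant to favour RNA of the cells that make the tagged protein. Per the labels' protocols, the mice were untreated controls, the tissue was homogenized, tagged polysomes were captured on magnetic beads, and RNA was purified from the immunopurified fraction. All 4 libraries formed 1 group and carried the replicate numbers 1 to 4 of their titles. The description of the library titled replicate 4 ends with the replicate label of replicate 3, under a library number of its own. The title was followed, and the counts of these 2 libraries differed far beyond sampling noise (chi-square of 215 per degree of freedom), so they were kept as separate replicates. Libraries of the unbound or total RNA were not used here, so levels are given within the immunopurified RNA, and enrichment over the tissue was not measured. The labels do not say whether the replicates came from separate animals or pools, and p-values therefore measure the spread between these libraries, which may be technical.

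The deposited values were raw read counts per gene symbol, with no normalization. Per the submitters' processing notes, reads were processed with STAR 2.0.0e and HTSeq on mm10. The annotation, the strand setting and the counting options were not given in the sources used here, so reads of overlapping or antisense genes could not be told apart, and reads of near-identical gene copies were treated as uncertain. Each table also held 5 HTSeq summary rows, which were kept out of library sizes and tests. Reads outside any annotated feature made up 24.0% to 30.1% of the total of a library, reads with more than 1 alignment 28.6% to 37.2%, and ambiguous reads 1.25% to 2.07%. A further row with the name unknown held 0 counts in every library. The tables of replicates 1 and 2 listed the same 32531 gene rows, and those of replicates 3 and 4 the same 32657. The 2 sets shared 31735 rows, which were analysed. Rows present in only 1 set held 0.549% to 0.732% of the gene counts of a library. Neither set had rows for mitochondrially encoded genes, and Hba-a1, Hbb-bt and Scn2a had no shared row. No columns of other series were present.

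Library totals over gene rows were 21140265, 15556918, 12731825 and 15315942 counts in replicates 1 to 4. Levels are in CPM, the counts of a gene per 1000000 counts of its library. One count was worth 0.0473 to 0.0785 CPM, and a count of 0 allows a level of up to 3 counts, or 0.142 to 0.236 CPM. Such floors and all counting intervals cover counting error only, since reads without molecular identifiers are not independent molecules. CPM were computed from these totals. To compare genes with each other, CPM were divided by the union exon length of the gene in kilobases from GENCODE M21 (GRCm38, the same assembly as mm10). Length was found by symbol for 23086 shared rows, which include 95.3% of the genes at 1 CPM or more in all 4 libraries. The union of exons can be longer than the transcripts in use, and such genes then read low. Log2 values had a pseudocount of 0.5 CPM per kb. The libraries were compared with each other by a chi-square test of their counts over 10632 genes, and no pair was close to sampling noise.

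Choices made before the data were examined were the 34 gene lists, the 20 gene pairs, the tests and the rule for named genes. The level of a list in a library was the median log2 value of its members, and its percentile was taken among 10000 random lists of the same size drawn from the genes detected in at least 1 library. A second percentile, not set in advance, was taken among lists drawn from the 10131 genes with a length that reached 1 CPM in all 4 libraries, called genes detected throughout. Gene pairs were compared by the log2 ratio within each library with a two-sided exact sign-flip permutation test. With 4 libraries this has 16 sign patterns and a smallest p of 2 in 16, so it cannot reach 0.05. Pairs are therefore described by the direction in each library and by whether the mean is over 2 SD.

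The descriptions number the libraries as 1666 and 1667 (replicates 1 and 2, the first pair) and 2469 and 2470 (replicates 3 and 4, the second pair). The labels name no batch, and the pairs were inferred from these numbers. The second pair was compared with the first by edgeR 4.0.16 (TMM, filterByExpr, quasi-likelihood F test, Benjamini-Hochberg threshold of 0.05). Lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01, with an estimated correlation, and with fry. Alternatives set before the data were examined were DESeq2 1.42.0, its size factors within edgeR, 2 other filters, removal of the 20 most abundant genes, other pseudocounts and detection limits, CPM without length, means in place of medians, and leaving out each replicate in turn. With a replicate left out, 1 pair holds a single library, whose spread is assumed to be that of the other pair. Alternatives added after seeing the data were removal of Rn45s, joining of 237 renamed rows, and a correction for GC content and transcript length. The correction fitted a loess curve (span 0.5) per library to the log2 CPM of 12864 genes (92.5% of those tested), centred on the mean of each gene. Such a fit also removes any real difference that follows GC content.

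Genes were named by a fixed rule. Levels were given for Cbln2 and its family, Rpl10a, the genes of the pairs, the 20 most abundant genes, and up to 5 members of each list with the highest mean CPM, plus members near 0 where absence is stated. For the library pairs the rule took the 10 largest changes in each direction among genes with an adjusted p under 0.05, a mean of at least 5 CPM and no overlap between the pairs, plus up to 3 called members per list. For variability it took the 10 genes with a mean of at least 20 CPM and the largest SD of log2 CPM. Members named outside the rule are said to be so. Some genes that the rule takes are not reported here, so the genes named can be fewer than a count given for them.

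The pair test was tested on simulated counts for 13905 genes with 200 changed genes. With the dispersion estimated from these libraries, it recovered 33% of changes of log2 size 2 and 82% of changes of log2 size 4, with 7 unchanged genes called. With 0.1 of that dispersion it recovered 96% and 100%. The list percentile was tested on 5000 simulated genes, where 6% of unchanged lists lay above the 95th percentile. Python 3.11.15, pandas 2.3.3, scipy 1.17.1, R 4.3.3 and matplotlib 3.10.9 were used.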

Results

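Ribosome-bound RNA was profiled in 4 immunopurified libraries of the rostral pons of untreated adult mice of a line in which Cbln2 drives EGFP-tagged ribosomal protein L10a. Cbln2 encodes cerebellin 2, a secreted protein that links presynaptic neurexins to postsynaptic delta glutamate receptors. The series has 1 group of immunopurified RNA, so the results are levels, ratios between genes within a library, and differences between replicates. The libraries held 12731825 to 21140265 gene counts. In all 4 libraries 10632 genes reached 1 CPM, 6437 reached 10 CPM and 1331 reached 100 CPM. Across genes, log2 CPM correlated at 0.872 and 0.874 (Pearson) within the pairs of adjacent library numbers and at 0.798 to 0.815 between them. Genes are not independent replicates, so these values describe the libraries only.

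The cerebellin family was detected as a whole, and Cbln1 exceeded the gene that gives the line its name. Genes of cerebellar granule cells, Cbln3 among them, were present too. In the second library pair the log2 change of Cbln1 was -1.49, beside a median of -2.09 for the granule list. The cerebellin levels and ratios therefore cannot be assigned to the tagged cells alone. Cbln2 (ENSMUSG00000024647.14, chromosome 18, 86711110 to 86718283, plus strand, GRCm38) was at 135 ± 74.0 CPM (SD, n = 4), with 239, 110, 126 and 65.7 CPM in replicates 1 to 4. Cbln1 (chromosome 8, 87468405 to 87472609) was at 830 ± 483 CPM, Cbln3 (chromosome 14, 55878913 to 55884392) at 132 ± 123 and Cbln4 (chromosome 2, 172036233 to 172043466) at 58.1 ± 32.0. Per kb of exon, the log2 ratio of Cbln2 to Cbln1 was -2.49 ± 0.58 (SD), below 0 in 4 of 4 libraries, so that Cbln2 stood at 0.178 of Cbln1. Cbln2 was 2.27 times Cbln4 (log2 1.18 ± 0.25, above 0 in 4 of 4), while its ratio to Cbln3 was above 0 in 3 of 4 libraries and within its spread (log2 1.17 ± 1.46). The exact sign-flip p, adjusted over 20 pairs, was 0.156 for Cbln1 and Cbln4, the smallest that 4 libraries allow, and 0.278 for Cbln3. The binding partners of cerebellins were detected too. Nrxn3 was at 460 ± 134 CPM, and the receptor gene Grid1, outside the rule for named genes and chosen for its known binding, at 19.7 ± 8.78. All 9 genes of the cerebellin list reached 1 CPM in all 4 libraries, and its median lay at the 98.0th to 99.99th percentile of random lists (87.9th to 99.89th among genes detected throughout).

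Reads of Rpl10a (chromosome 17, 28328471 to 28331033) can come from the tag as well as from the gene. Rpl10a was at 101, 134, 225 and 152 CPM in replicates 1 to 4. It exceeded the median of the other large ribosomal protein genes per kb by a log2 ratio of 0.37 ± 0.24 (SD, n = 4) and ranked 22, 12, 12 and 21 among 44 genes. In replicate 4 the log2 ratio was 0.02. Without the division by length the mean log2 ratio was 0.82. Many ribosomal protein genes have near-identical pseudogenes, so these counts are uncertain. Rpl26 was at 0 counts in all 4 libraries.

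The transmitter genes were led by Slc17a6 (chromosome 7, 51622006 to 51671119), which encodes the vesicular glutamate transporter VGLUT2. It was at 408 ± 83.3 CPM, or 75.5 ± 15.4 CPM per kb (SD, n = 4). It exceeded Slc17a7 (VGLUT1) 18.0-fold (log2 4.17 ± 0.80) and Slc17a8 (VGLUT3) at least 102-fold (log2 6.68 ± 0.60), each in 4 of 4 libraries. Slc17a8 was at 0 counts in replicates 2 and 3 and below the pseudocount on average, which sets that ratio. Other genes of glutamate transmission were abundant, with the AMPA receptor gene Gria2 at 406 ± 116 CPM and the NMDA receptor gene Grin1 at 160 ± 111. Genes of inhibitory transmission were present as well. Gad2, which makes GABA, was at 299 ± 165 CPM and Gad1 at 103 ± 71.0. Slc17a6 exceeded Gad1 6.70-fold (log2 2.74 ± 1.03) and the vesicular GABA and glycine transporter gene Slc32a1 15-fold (log2 3.91 ± 1.36) in 4 of 4 libraries. Against Gad2 its log2 ratio was 0.74 ± 0.78, above 0 in 3 of 4 libraries and within the spread. The forebrain interneuron genes Dlx1, Dlx2 and Dlx5 were at 0 counts in all 4 libraries.

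The glycine transporter gene Slc6a5 was low, with 1.04, 2.83, 0.314 and 37.8 CPM in replicates 1 to 4, and Slc32a1 exceeded it in 4 of 4 libraries (log2 ratio of Slc6a5 to Slc32a1 -2.10 ± 0.78). The glycine receptor genes Glrb, Glra2 and Glra1 were at 217 ± 89.6, 113 ± 51.4 and 106 ± 52.2 CPM, and the receptor anchor gene Gphn at 57.2 ± 11.4. Chat, which makes acetylcholine, was at 1.56, 0.836, 22.3 and 25.7 CPM, and Slc17a6 exceeded it 36.5-fold (log2 5.19 ± 1.95). The choline transporter gene Slc5a7 was at 85.9 ± 55.1 CPM. Noradrenaline genes were low and uneven. Dbh was at 3.36, 1.03, 2.20 and 61.1 CPM, Th (chromosome 7, 142892752 to 142931128) at 2.84, 0.643, 34.5 and 42.5, and the noradrenaline transporter gene Slc6a2 at 56.6, 16.3, 23.6 and 137. The vesicular monoamine transporter gene Slc18a2 was at 37.8 ± 36.9 CPM. Serotonin genes were low too, with Tph2 at 8.98 ± 9.14 CPM and Slc6a4 at 0.0473, 0, 0 and 5.42. Slc17a6 exceeded Tph2 26.8-fold (log2 4.74 ± 1.33) and Dbh 28.5-fold (log2 4.83 ± 2.21) in 4 of 4 libraries. For Th the mean was 17.1-fold in 4 of 4 libraries, but under 2 SD (log2 4.10 ± 2.55). Neither Tph2 against Dbh (log2 0.09 ± 1.35) nor Th against Dbh (0.74 ± 1.86) differed by more than the spread, and the sign of both turned without replicate 3, to -0.23 and -0.19. Without replicate 2 the log2 ratio of Tph2 to Dbh was -0.33. Each of these ratios that went one way in 4 of 4 libraries had an adjusted exact sign-flip p of 0.156.

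**Figure D1:**
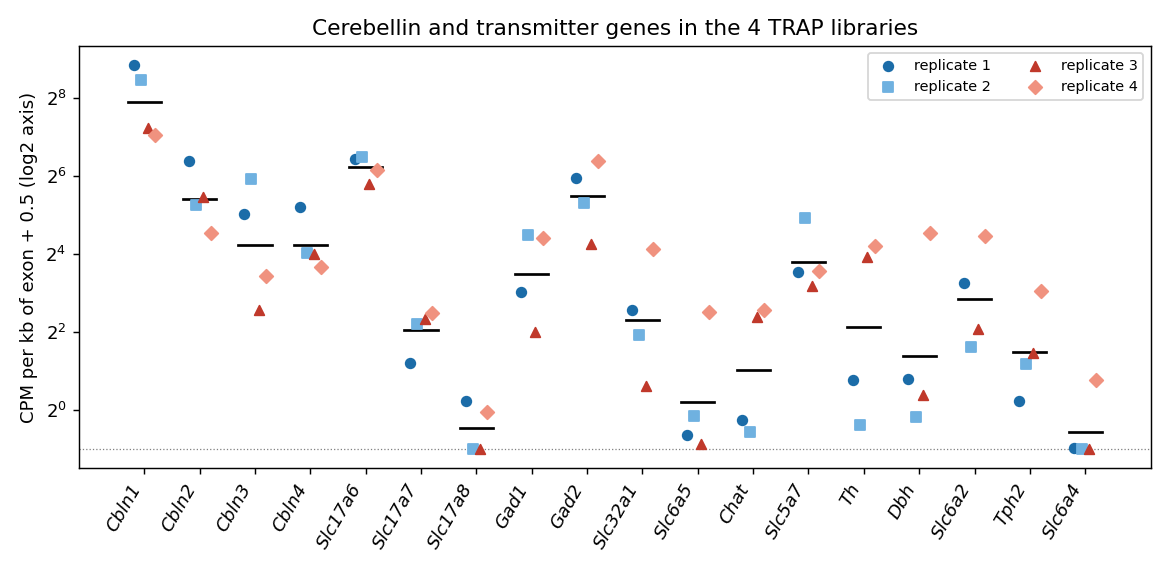
Levels of cerebellin and transmitter genes in each of the 4 libraries, as CPM per kb of exon plus 0.5 on a log2 axis; symbols are replicates, black bars are the mean of the log2 values, and the dotted line marks 0 counts. Slc17a6 lies at 75.5 ± 15.4 CPM per kb (mean ± SD), while Dbh and Slc6a5 are high in replicate 4 and Th and Chat in replicates 3 and 4.

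The general neuronal list lay far above the lists of non-neuronal cell types. The lists hold different genes and no unpurified RNA was compared, so the margins do not measure purity. The list of general neuronal genes, among them Snap25, Syn1, Nefm, Nefl and Map2, had a median log2 level of 6.56 ± 0.31 (SD, n = 4) and lay above all 10000 random lists in every library. It exceeded the astrocyte list by 3.89 ± 0.87, the oligodendrocyte list by 3.34 ± 1.07, the oligodendrocyte precursor list by 5.77 ± 0.63, the microglia list by 6.72 ± 0.60 and the endothelial list by 5.15 ± 1.21 on the log2 scale. The margin was 6.08 ± 0.16 over mural and leptomeningeal genes, 7.18 ± 0.12 over ependymal and choroid plexus genes, and 5.44 ± 1.41 over the 3 measured blood genes. All 8 differences were above 0 in 4 of 4 libraries, which gives the smallest exact sign-flip p that 4 libraries allow (2 of 16 sign patterns). Rbfox3, the gene of the neuronal antigen NeuN, exceeded the astrocyte gene Aldh1l1 31.7-fold (log2 4.99 ± 0.71), the microglia gene Csf1r 24.9-fold (4.64 ± 1.89) and the endothelial gene Cldn5, at 0 counts in replicate 4, at least 40.5-fold (5.34 ± 0.96). Its ratio to the oligodendrocyte gene Mog was above 0 in 4 of 4 libraries but under 2 SD (2.65 ± 2.26).

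Some glial genes were nevertheless abundant. The oligodendrocyte list lay at the 62.8th to 99.91th percentile of random lists (5.57th to 98.23th among genes detected throughout). The astrocyte list lay at the 49.8th to 98.6th (1.65th to 84.11th among genes detected throughout). In replicates 1 to 4 the astrocyte glutamate transporter gene Slc1a2 was at 591, 654, 184 and 1304 CPM, and the myelin gene Mbp was at 366, 355, 237 and 1147 CPM. Glutamine synthetase Glul was at 561 ± 302 CPM and the water channel gene Aqp4 at 139 ± 100. The vascular genes Slc2a1, Rgs5 and Flt1 were at 90.8 ± 26.1, 65.5 ± 24.3 and 43.4 ± 17.7 CPM. Of the 12 microglia genes, 2 reached 1 CPM in all 4 libraries, and Csf1r was at 12.8, 0.579, 1.34 and 26.2 CPM. None of the 10 ependymal and choroid plexus genes reached 1 CPM in all 4 libraries, and Ttr was at 0, 2.89, 1.41 and 106 CPM.

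Genes of the neighbouring cerebellum were present. All 8 granule cell genes reached 1 CPM in all 4 libraries, and their median lay at the 84.0th to 100th percentile, and at the 43.0th to 99.97th among genes detected throughout. Besides Cbln3, they include Zic1 at 67.6, 299, 38.6 and 44.1 CPM and Gabra6, outside the named rule and chosen as a granule cell receptor gene, at 82.0, 122, 13.7 and 37.4. The Purkinje cell and Bergmann glia list lay at the 91.3th to 99.97th percentile (62.9th to 99.80th among genes detected throughout), with Itpr1 at 860 ± 622 CPM and Car8 at 246 ± 240, while the Purkinje cell gene Pcp2, outside the named rule, was at 5.49 ± 4.49. Forebrain genes were at the 0.62th to 2.03th percentile (0 among genes detected throughout), with Emx1 at 0 counts in all 4 libraries.

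**Figure D2:**
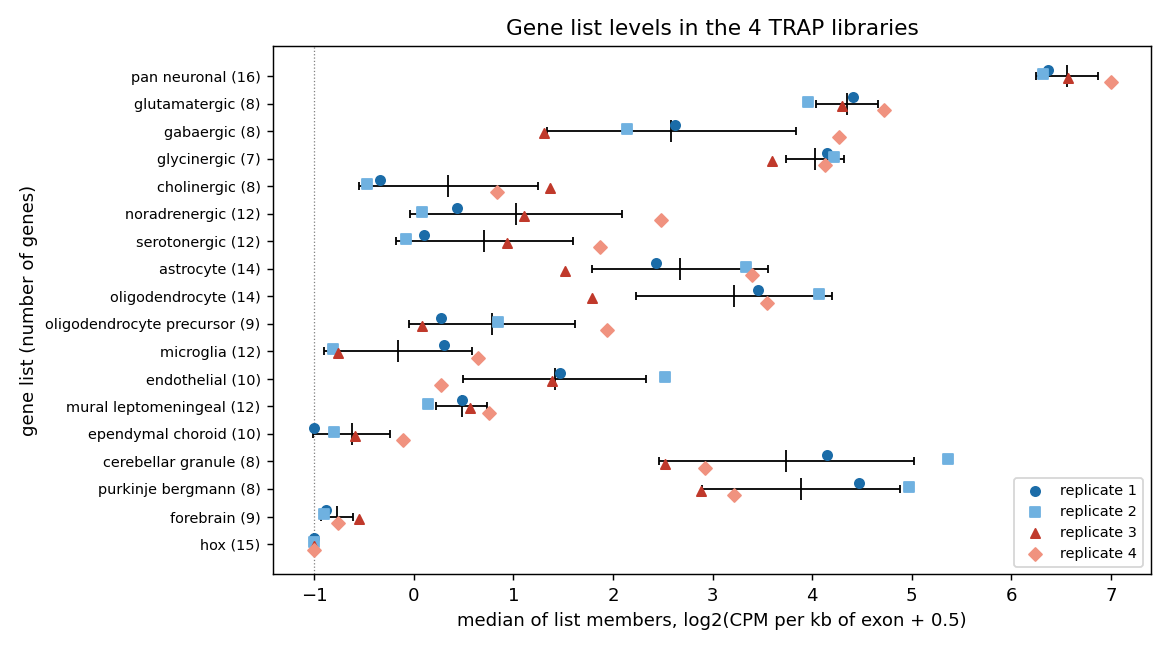
Median log2 level (CPM per kb of exon plus 0.5) of 18 gene lists in the 4 libraries, with the number of genes in parentheses; points are replicates, vertical ticks the mean, horizontal bars the SD, and the dotted line marks 0 counts. General neuronal genes lie highest at 6.56 ± 0.31, and the cerebellar granule list is higher in replicates 1 and 2 than in replicates 3 and 4.

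A minority of the neuropeptide genes was detected throughout. Of 47 neuropeptide and granule protein genes, 15 reached 1 CPM in all 4 libraries and 14 were at 0 counts in all 4, which allows up to 0.142 to 0.236 CPM per library. The secretogranin gene Scg2 was at 1087 ± 342 CPM (SD, n = 4) and the chromogranin gene Chgb at 456 ± 278. Among peptide precursors, Tac1 (substance P) was at 422 ± 297 CPM, Adcyap1 (PACAP) at 274 ± 82.5 and Penk (enkephalin) at 264 ± 85.4. Calca, which encodes calcitonin gene-related peptide, was chosen outside the rule as a marker of the parabrachial region, and was at 208, 60.2, 138 and 88.4 CPM. Trh and Tac2 were at 0 counts in all 4 libraries, and Pdyn and Npy had means of 0.330 and 0.546 CPM.

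Transcription factor genes of the hindbrain included Zfhx3 at 446 ± 56.6 CPM, Ebf3 at 418 ± 189, Zfhx4 at 344 ± 84.1 and Ebf2 at 342 ± 187 (SD, n = 4). Of the 60 genes on this list, 34 reached 1 CPM in all 4 libraries. The list as a whole was not high, with its median at the 0.75th to 57.1th percentile of random lists (0 among genes detected throughout). En1, which marks the midbrain and the rostral hindbrain, was at 33.8 ± 11.9 CPM, and Lmx1a, named after its values were seen, at 42.4 ± 18.4. Hox genes, which pattern the hindbrain behind its first segment, were nearly missing. None of 15 reached 1 CPM in all 4 libraries and 6 were at 0 counts in all 4. The highest on average, Hoxa2, was at 0.331, 0.836, 0.0785 and 4.05 CPM.

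The most abundant row on average was Rn45s, a row named for the ribosomal RNA precursor. It came after Snap25 and Malat1 in replicate 1, and held 1.68%, 1.61%, 24.2% and 9.29% of the gene counts of replicates 1 to 4. Reads of mature ribosomal RNA were not told apart from those of the precursor. The row takes its share from the CPM of every other gene. Other abundant rows were the synaptic gene Snap25 at 12388 ± 5731 CPM (SD, n = 4), the microtubule gene Map1b at 9169 ± 2745, the nuclear RNA Malat1 at 7607 ± 6614, and the calcium sensor gene Vsnl1 at 5727 ± 3219. Gnas varied less, at 3129 ± 288 CPM. Among the 20 genes that follow Rn45s were also Ywhaz, Cdr1, Rtn1, Tubb4a, Kif1a, Ndrg4, Calm2, Camta1, Ttc3, Map1a, Peg3, Lars2 and AK140265, between 1809 and 3637 CPM on average. The largest SDs of log2 CPM among genes of at least 20 CPM on average were those of Adnp (5.41), Mir6236 (4.42), Ubb (4.31), 3110039I08Rik (3.95) and Ttr (3.29). Ddx3y, Rab1b, Gnb2, Sept9 and Acvr2b followed at 3.18 to 2.95.

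The replicates of the higher library numbers (3 and 4, the second pair) differed from those of the lower numbers (1 and 2, the first pair) in 176 of 13905 tested genes, of which 99 were higher and 77 lower in the second pair (edgeR quasi-likelihood test, adjusted p under 0.05). This measures differences between replicates of 1 group, with 2 libraries on each side, and no treatment is involved. The count was 699, 662, 420 and 389 without replicates 1, 2, 3 and 4 in turn, and 1386 by DESeq2. In the second pair Nos1 (neuronal nitric oxide synthase) rose from 7.36 to 210 CPM, a log2 change of 4.84 with SE 0.44 and an edgeR adjusted p of 0.000349. Ubb, a polyubiquitin gene with near-identical copies, rose from 1.28 to 298 CPM (log2 7.85, SE 0.56, edgeR adjusted p = 2.56e-05). The row Mir6236 rose from 6.88 to 1527 CPM. Abat, which breaks down GABA, rose by a log2 value of 3.21 (SE 0.42, edgeR adjusted p = 0.00614), from 40.6 to 380 CPM. The row 3110039I08Rik was at 0 counts in the first pair and at least 696-fold higher in the second, against a floor of 3 counts over the pair. Apex1, a DNA repair gene, had 1 count in the first pair and 698 in the second, a ratio of 913 (95% exact interval 163 to 36123). Pdgfb had 3 and 520 counts, a ratio of 227 (77.2 to 1103). Atp5g2, Ap2s1, Plk3 and Txn2 rose by log2 values of 7.16, 6.69, 6.61 and 4.96. Without replicate 4 Pdgfb and Txn2 were not called (adjusted p = 0.58 and 0.0724), and without replicate 3 Plk3 was not (0.28).

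In the second pair Adnp, a homeobox gene, had 1 count against 12767 in the first, a ratio of 9758 (95% exact interval 1751 to 385445). The row mKIAA0217, the Y-linked gene Kdm5d (chromosome Y, 897788 to 956786) and Smok4a were at 0 counts in the second pair and at least 346-fold, 276-fold and 137-fold lower there. AK009977 had 1 count against 579, a ratio of 443 (79.1 to 17509). AK140446 fell by 4.46 on the log2 scale and the zinc finger gene Ikzf5 fell by 4.38. Neurod1 (chromosome 2, 79452521 to 79456751), a transcription factor gene of cerebellar granule cells, fell by 3.75 (SE 0.57, edgeR adjusted p = 0.0127), from 152 to 11 CPM. The glypican gene Gpc6 fell by 3.16 and Nrep by 2.93. Among the list members that fell, log2 changes were -2.85 for Car8, -2.58 for Cbln3, -2.56 for Nefm, -1.94 for Gria3, -1.75 for Itpr1, -1.69 for Tac1 and -1.49 for Cbln1, while Th rose by 4.47 and Tubb3 by 1.97. Cbln2 did not pass the test (log2 change -0.80, SE 0.48, edgeR adjusted p = 0.442). The pairs were counted against gene row sets that differ in 796 and 922 rows. In this comparison 11 genes, among them Adnp, Kdm5d, mKIAA0217, 3110039I08Rik, Apex1, Ap2s1, Atp5g2 and Plk3, were under 0.5 CPM in both libraries of one pair and at 10 CPM or more in both of the other. Leaving out 1 replicate ended some calls, with adjusted p of 0.056 for Cbln1 and 0.0776 for Tac1 without replicate 1, 0.0899 for Itpr1 and 0.211 for AK009977 without replicate 2, and 0.0512 for Ikzf5 without replicate 4.

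By camera with a preset correlation, 6 of 32 tested lists differed between the pairs, none with an estimated correlation. The large ribosomal protein list rose, with a median log2 change of 0.96 over 43 genes (adjusted p = 0.000172, and adjusted p = 0.752 with an estimated correlation). Of its members 3 rose over all genes tested and 16 adjusted over the list alone. They were Rplp1, Rpl28 and Rplp2, with log2 changes of 3.29, 2.72 and 2.51, and Rpl28 was not called without replicate 3 (adjusted p = 0.0554). The cerebellar granule list fell, with a median of -2.09 over 8 genes (adjusted p = 0.00039, and adjusted p = 0.752 with an estimated correlation). Of its members, Neurod1 and Cbln3 fell over all genes tested and 7 adjusted over the list alone. Cbln3 is also on the cerebellin list, which did not pass (median -0.87, adjusted p = 0.124). The Purkinje cell and Bergmann glia list fell too, with a median of -2.0 over 8 genes (adjusted p = 0.0266, and adjusted p = 0.978 with an estimated correlation), with 2 members called over all genes and 3 adjusted over the list alone. Its call was lost without replicate 2 (adjusted p = 0.186), 3 (0.0551) or 4 (0.0711).

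The endothelial list fell with a median of -1.69 over 10 genes (adjusted p = 0.0131, and adjusted p = 0.978 with an estimated correlation), with 0 members called over all genes and 1 adjusted over the list alone, and was not called without replicate 2 (adjusted p = 0.186) or 4 (0.337). The sex-linked list fell with a median of -4.62 over 4 genes (adjusted p = 0.0131, and adjusted p = 0.752 with an estimated correlation), with 1 member called over all genes and 3 adjusted over the list alone, and was not called without replicate 1 (adjusted p = 0.118). Its median rests on Ddx3y and Uty. The cholinergic list rose with a median of 2.32 over 5 genes (adjusted p = 0.0492, and adjusted p = 0.752 with an estimated correlation). Of its members 0 were called over all genes and 2 adjusted over the list alone, with Chat at a log2 change of 4.33 (edgeR adjusted p = 0.0613). It was not called without replicate 1 (adjusted p = 0.172), 3 (0.168) or 4 (0.0602), nor without Rn45s (0.0506). The astrocyte, oligodendrocyte and microglia lists did not pass (adjusted p = 0.359, 0.344 and 0.921).

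The difference between the pairs moved in part with GC content. Across genes, the rank correlation of the log2 change with GC content was 0.374 (Spearman). A polynomial fit on GC content and transcript length accounted for 11.8% of the variance of the log2 change, so most of it did not follow them. In 5 equal bins of genes from low to high GC content, the median log2 change was -0.39, -0.35, -0.16, 0.32 and 0.96. Slopes on GC content were taken from log2 CPM centred on the mean of each gene over the 4 libraries. They had one sign in replicates 1 and 2 (-0.44 and -0.37 per 10 percentage points) and the other in replicates 3 and 4 (0.43 and 0.38). Centring makes slopes of both signs unavoidable, so they compare the libraries with each other only. It does not fix which libraries share a sign. Rn45s, taken for its abundance, rose from 16478 to 167567 CPM between the pairs (log2 3.41, SE 0.42, edgeR adjusted p = 0.00576). After a correction for GC content and transcript length, 70 genes were called, 15 higher and 55 lower, where the same 12864 genes gave 114 higher and 90 lower without it. It moved the median of all genes from -0.01 to -0.11. Of the named genes, 15 lost their call under it, but 11 of these kept over 0.75 of their log2 change (median 0.837) and the SE was about as before (median ratio 0.96). The log2 change shrank most for Tubb3 (1.98 to 1.02, adjusted p = 0.209), Rplp1 (3.30 to 1.91, 0.157), Rplp2 (2.53 to 1.51, 0.201) and Rpl28 (2.74 to 2.02, 0.0794). It shrank less for Atp5g2 (7.17 to 5.50, 0.087), Gria3 (-1.93 to -1.48, 0.108), Tac1 (-1.67 to -1.39, 0.0797), Ap2s1 (6.71 to 5.61, 0.0794), Plk3 (6.63 to 5.57, 0.0747) and Pdgfb (7.56 to 6.40, 0.0862). It was nearly kept for Th (4.48 to 3.99, 0.0755), Ikzf5 (-4.37 to -3.93, 0.0755), Txn2 (4.98 to 4.49, 0.0755) and Smok4a (-10.79 to -10.72, 0.0536). Nos1, Ubb, Abat, Adnp, Neurod1, Cbln3, Car8, Cbln1, Nefm, Mir6236, 3110039I08Rik, Apex1, Kdm5d, Gpc6, Nrep and Itpr1 stayed past the threshold. The other named rows had no GC value. Of the lists, the endothelial (adjusted p = 0.0192), cerebellar granule (0.00292) and sex-linked (0.0372) ones stayed past it with the preset correlation, each at an adjusted p = 0.816 with an estimated correlation. The other 3 did not. Their median log2 change went from 0.97 to 0.31 for the ribosomal protein list (adjusted p = 0.0511), from 2.33 to 1.06 for the cholinergic list (0.061), and from -1.99 to -2.16 for the Purkinje list (0.0511), whose call ended although its median did not shrink.

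**Figure D3:**
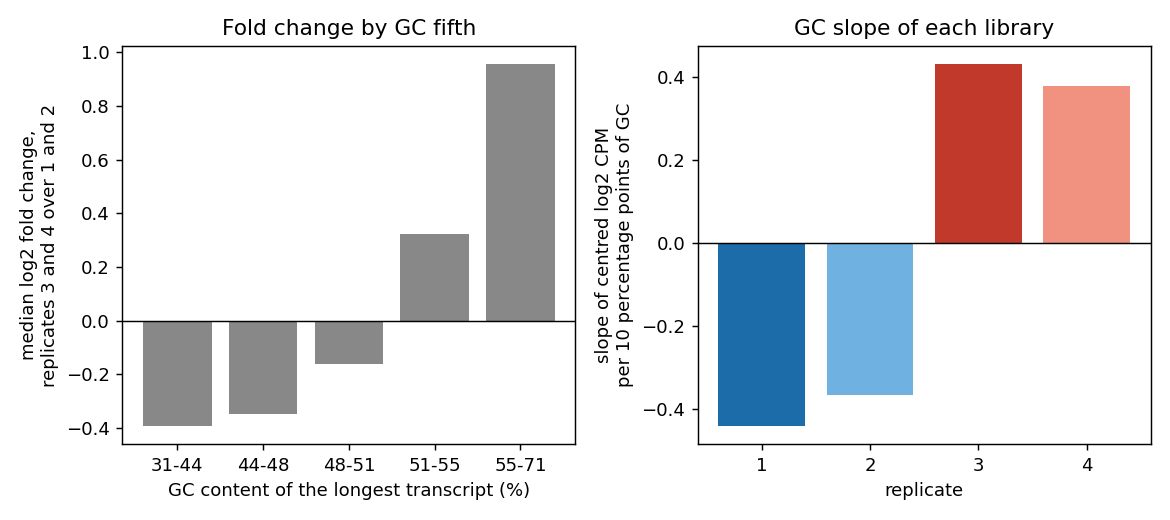
Left, median log2 fold change of replicates 3 and 4 over replicates 1 and 2 in 5 equal bins of genes by GC content of the longest transcript (percent). Right, slope of the centred log2 CPM on GC content in each library, per 10 percentage points. The medians run from -0.39 in the lowest GC bin to 0.96 in the highest, and the slopes are below 0 in replicates 1 and 2 and above 0 in replicates 3 and 4.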

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

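A value was marked where the gap between 1 library and the nearest other exceeded Dixon's 95% critical value for 4 samples. Of 256 values tested, 26 were marked, 22 of them among 198 levels of named genes. A rate of 1 in 20 would give about 12.8, but it holds for normally distributed values chosen without regard to their spread. The named genes include those with the largest SD over these libraries and list members with the highest mean CPM, which 1 high library can raise. The 26 marks therefore cannot be weighed against 12.8. No test in this part was chosen after the result was seen, and the values are given without explanation.

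Replicate 4 stood above the other 3 libraries for genes of several cell types. Dbh was at 61.1 CPM against 1.03 to 3.36, Slc18a2 at 92.6 against 15.6 to 26.7, Slc6a5 at 37.8 against 0.314 to 2.83, Ttr at 106 against 0 to 2.89 and Kl at 12.5 against 0 to 1.65. Mbp was at 1147 CPM there against 237 to 366, C1qb at 8.88 against 0.628 to 1.04, and Tbr1 at 8.55 against 0.157 to 0.237. Hoxb3 was at 2.61 CPM against 0 to 0.142 and Hoxb4 at 3.26 against 0 in the others. The median log2 level of the neuropeptide list was 0.51 in replicate 4 and -0.77 to -0.66 in the others.

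Replicate 3 stood apart for the log2 ratio of Th to Dbh (3.52 against -0.33 to -0.04) and of Rbfox3 to Mog (6.04 against 1.44 to 1.59). Its glycinergic list level was lowest (3.59 against 4.13 to 4.22), as was Nrxn3 at 260 CPM against 513 to 546. Rn45s held 24.2% of the gene counts of replicate 3, against 1.61% to 9.29% in the others, and lowers the CPM of other genes there by its share. These levels include Rn45s in the library total, so the small gap of the glycinergic list cannot be told apart from that share. Lhx2 was at 6.13 CPM and Hoxd3 at 1.89 in replicate 3 and both at 0 in the others.

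Replicate 2 stood apart for Zic1 (299 CPM against 38.6 to 67.6), Slc5a7 (168 against 48.5 to 64.4), Pou4f1 (16.8 against 1.65 to 4.05), Peg3 (2233 against 1624 to 1721) and Insr (46.7 against 76.4 to 81.2). Replicate 1 stood apart for Cbln4 (105.7 CPM against 35.6 to 46.1), Lhfpl3 (117 against 59.1 to 67.6) and Eif2s3y (8.61 against 0 to 0.579).

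Gene rows listed in the tables of only 1 pair of libraries were left out of the main comparisons. They held up to 0.732% of the gene counts of a library, in replicate 2.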

How the results depend on the processing

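Removal of Rn45s, joining of renamed rows and the GC and length correction were chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because the series has 1 group and its 4 replicate numbers are all different. The number of genes detected stayed within 1.5 times its value under all 9 alternatives. The differences between neuronal and other lists kept their direction throughout. With CPM not divided by length they moved by over 1 SD to 8.73 (microglia), 6.68 (mural), 9.27 (ependymal and choroid) and 7.88 (blood). With a pseudocount of 0.1 they were 7.82 (microglia), 6.59 (mural) and 8.76 (ependymal and choroid), and with a pseudocount of 1 they were 6.05, 5.63 and 6.36. The mean of members gave 7.06 for ependymal and choroid genes. These lists lie near the floor, where the pseudocount sets the level by construction. Of the gene pairs, 4 moved by over 1 SD in 7 results, most with a gene near the pseudocount. Slc17a6 over Slc17a8 was 8.32 without division by length, 8.17 with a pseudocount of 0.1 and 5.91 with a pseudocount of 1. Slc6a5 over Slc32a1 was -2.99 with a pseudocount of 0.1, and Rbfox3 over Cldn5 was 6.51 with it and 7.66 without division by length. Without division by length Rbfox3 over Aldh1l1 was 5.97 and Rpl10a over the other large ribosomal protein genes 0.82. The log2 ratio of Tph2 to Dbh turned from 0.09 to -0.0033 with a pseudocount of 1, and with 1 replicate left out ran from -0.33 (without replicate 2) to 0.62 (without replicate 4), with -0.23 without replicate 3. That of Th to Dbh ran from -0.19 (without replicate 3) to 1.10 (without replicate 4). Neither pair differed beyond its spread.

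Between the library pairs, 176 genes became 875 with no filter on low counts, 306 with a mean of at least 5 CPM, 1386 with the DESeq2 Wald test, 70 with the GC and length correction, and 389 to 699 with 1 replicate left out. All 176 were among the calls of DESeq2 and of both filters, and 51 among the 70. Higher and lower calls were 332 and 367 without replicate 1, 369 and 293 without 2, 189 and 231 without 3, and 171 and 218 without 4, against 99 and 77. These fits with 1 library on a side rest on the spread of the other pair, and the cause was not tested. The 6 called lists became 0 by camera with an estimated correlation (smallest unadjusted p = 0.0838), 1 by fry (cholinergic, adjusted p = 0.0478) and 3 with the GC and length correction. The cholinergic and Purkinje lists also lost their calls with a mean of at least 5 CPM (adjusted p = 0.118 and 0.082). For the named genes, 254 of 269 results under settings with all 4 replicates kept their call, and the 15 lost were lost under the GC and length correction, 11 of them with over 0.75 of their log2 change kept. With 1 replicate left out, 127 of 136 kept it. Depth limits genes near the floor of 0.142 to 0.236 CPM.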

Other observations

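Most transmitter receptor and channel genes were detected. Of the 45 GABA, glycine and glutamate receptor genes, metabotropic ones included, 42 reached 1 CPM in all 4 libraries, among them Gabbr1 at 523 ± 95.6 CPM (SD, n = 4) and Gabrb2 at 318 ± 115. Of 44 measured potassium, sodium and calcium channel genes, 43 did so, among them Kcna2 at 930 ± 401 CPM and Scn8a at 814 ± 420. Of 44 peptide receptor genes, 21 reached 1 CPM in all 4 libraries. The PACAP receptor gene Adcyap1r1 was at 146 ± 58.0 CPM beside its ligand gene Adcyap1, and the mu opioid receptor gene Oprm1 at 85.4 ± 11.4 beside Penk. Of 44 receptors for monoamines, acetylcholine, adenosine and cannabinoids, 22 reached 1 CPM in all 4, led by Htr2c at 174 ± 52.5 CPM, Adora1 at 125 ± 66.2 and the nicotinic gene Chrna4 at 70.5 ± 23.7.

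The large ribosomal protein and nuclear-encoded oxidative phosphorylation lists lay above all random lists in every library, with log2 levels of 5.62 ± 0.48 and 5.57 ± 0.18 and with Atp5b at 1684 ± 690 CPM. Heat shock genes were led by Hspa8 at 1315 ± 83.0 CPM and Hsp90aa1 at 1147 ± 190, and the list lay at the 56.4th to 99.85th percentile, and at the 4.67th to 98.28th among genes detected throughout. Immediate early genes were uneven, with Egr1 at 31.4, 23.9, 124 and 80.0 CPM and Fos, below the 5 highest members, at 9.20 ± 6.86; their list did not pass between the library pairs (camera adjusted p = 0.0509). The nuclear noncoding list lay at the 69.8th to 97.1th percentile (19.9th to 85.0th among genes detected throughout), with Meg3 at 970 ± 672 CPM. Genes of trigeminal sensory neurons were low, at the 3.60th to 16.1th percentile (0 to 0.04 among genes detected throughout), with Prph at 7.43 ± 8.72 CPM. Of the 9 noradrenergic genes tested, 5 (55.6%) were highest in replicate 4, against 30.0% of all tested genes. The log2 list levels of the serotonergic, noradrenergic and cholinergic genes were 0.71 ± 0.89, 1.02 ± 1.06 and 0.35 ± 0.90.

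Of the tests below, the count of genes near 0 in 1 pair was set out before its result was seen, and those of GC content, of other pairings and of the Y-linked genes were chosen after. The GC test on the called genes took several forms. Its first, the share still called after the correction (53 of 204, or 25.98%), lay between its bounds of 10% and 50% and decided nothing. The ratios below, their bounds and the split by direction were chosen later with GC results known, and over all 204 genes the ratio was 0.787, just past the bound of 0.75.

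Genes called between the library pairs are set against GC content, a change of annotation and other groupings, and no biological explanation was tested because the series has 1 group. Of the 204 genes called without the GC and length correction, 53 were still called with it. The 90 called lower had a median ratio of the log2 change after to that before of 0.906 (quartiles 0.808 and 1.04). Their median size was 1.86 before and 1.81 after, and 52 of them lost their call. These genes were selected for a large change before the correction. The median change of all genes in the lowest GC bins was only -0.39 and -0.35. A ratio under the bound of 0.5 was therefore hardly possible, and the ratio cannot decide whether the trend caused that set. For the 114 called higher the ratio was 0.657 (quartiles 0.524 and 0.804; median size 2.87 before and 1.82 after), between the bounds of 0.5 and 0.75, so the trend and other causes cannot be told apart for them, and the median of the large ribosomal protein list, which dropped from 0.97 to 0.31, fits the trend. Between the pairs 11 genes (among them Adnp, Apex1, Ap2s1, Atp5g2, Plk3 and Kdm5d) were under 0.5 CPM in both libraries of one pair and at 10 CPM or more in both of the other, against at most 4 under the other pairings; gene models that differ between the row sets may account for some, but 11 is not over 3 times 4, the bound set for it, and the models were not used here. The other 2 pairings gave 0 genes by edgeR (313 and 270 at an unadjusted p under 0.05) against 176 (2334), and 3 pairings are too few to weigh chance, since 1 of 3 is the smallest share possible.

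The cerebellar granule genes were lower in the second pair. After the correction the median log2 change was -2.08 with all 8 genes below 0 (quartiles -2.60 and -1.57), where it was -2.08 before. The correction thus left this median unchanged. However, the median change of all genes in the lowest GC bins was only -0.39 and -0.35. Removing a trend of that size could hardly undo a fall of this size, so the test cannot decide whether GC bias was the cause. The ratio of granule to pontine tissue in the dissections is a hypothesis that stays open and was not tested, and whether some tagged cells are granule cells was not tested either. All 8 genes moved one way, and the list lost its call with an estimated correlation (adjusted p = 0.752).

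Y-linked genes were lower in the second pair. Kdm5d was at 30.3, 28.3, 0 and 0 CPM in replicates 1 to 4, and the sum of Ddx3y, Uty and Eif2s3y at 37.9, 99.2, 4.48 and 0 CPM. The highest sum in the second pair was 0.118 of the lowest in the first, which argues against a changed gene model of Kdm5d alone. Replicate 3 had 0 Kdm5d counts among 57 counts of the 4 Y-linked genes. Replicates 1 and 2 had 641 of 1442 and 441 of 1984. A changed gene model of Kdm5d in addition is therefore not excluded. Xist, the X-inactivation RNA of females, was at 308, 70.9, 71.6 and 403 CPM, so that replicates 1, 2 and 3 held both kinds of transcript and replicate 4 held no Y-linked count. The sex of the mice is not in the labels, and a different mix of females and males in each library is a candidate explanation that stays untested.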
